A study of Mus musculus with 6 samples.

How the data were processed

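The deposited table held log2 probe-set intensities that, per the submitters' processing notes, came from RMA (version not given) applied to Affymetrix 1-colour arrays. Per the labels, RNA of T cells purified from individual spleens was amplified with a kit that primes with oligo(dT) and random primers, and labelled with biotin. Values were used as deposited, without further transformation, filter or pseudocount. The labels name individual spleens, so replicates are separate animals, and the 6 arrays were grouped by the genotype in their labels, 3 KO and 3 WT. The labels pair no samples. Of 45101 probe sets 64 were array controls and 45037 were tested. The annotation supplied with the platform gave 1 gene for 34945 of them and several genes for 932, and it did not list 9160. Of those with 1 gene, 34741 were matched by Entrez ID to the GRCm38.p6 gene table, and 0 symbols changed. Each of 18194 genes was represented by its probe set with the highest mean over the 6 arrays. Of these probe sets 1580 have the suffix _s_at or _x_at and can cross-hybridise with related genes, among them those of S100a8, Lyz1 and Klra7. RMA values carry no detection calls, so differences of dim probe sets are understated.

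R 4.3.3 and limma 3.58.1 were used. A model with genotype as its term was fitted with lmFit and eBayes without trend, and two-sided p values were adjusted with the Benjamini-Hochberg method over all 45037 probe sets. Rose, fell and changed stand for an adjusted p below 0.05, and differences are KO minus WT on the log2 scale with the moderated standard error. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 38 lists, with camera at an estimated correlation and fry beside it. The 38 lists (26 of pathways and T cell states, 12 of cell type markers), the threshold, the test and the alternatives were fixed before the data were examined, except scaling to the 18 hybridization control probe sets and leaving out WT replicate 1 with KO replicate 2, which were chosen after seeing the data.

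The lists covered E2F, pocket protein and DREAM components, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and cyclin D, p53 targets and DNA damage, the BCL2 family and caspases, reported miR-142 targets, naive and quiescence genes, activation, effector and memory genes, regulatory T cells, helper subsets, coinhibitory receptors, the T cell receptor complex, CD8 and CD4 lineage genes, cytokine receptors, TGF-beta signalling, interferon-stimulated genes, actin, adhesion and chemokine receptors, cyclic AMP signalling, glycolysis and MYC, oxidative phosphorylation, the microRNA pathway, immediate early genes and the clock. Cell type lists covered B cells, plasma cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, NK cells, gamma delta T cells, progenitors with stroma and immature thymocytes. They were written from general knowledge.

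Named genes were Mir142, E2f7 and E2f8, the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold whose 3 KO values all lay on one side of the 3 WT values, and in each list up to 4 members past the threshold with the largest differences, leaving out predicted genes and receptor variable segments. Genes outside this rule are named only where few members of a list went one way, and the text says at each that its choice came after its values were seen.

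Alternatives were a filter on probe sets below the median mean level of 5.77, a repeated quantile normalization, centring on array medians, an intensity trend with robust fitting, array weights, the replicate number as a block, an adjusted p below 0.10, a minimum change of 1.5-fold, leaving out each array in turn, the mean of a gene's probe sets, and each named gene's other probe sets. Where leaving out an array left 2 in a group, limma pooled the spread over both groups. All 10 splits of the 6 arrays into 3 and 3 were fitted. As a self-test, 200 of 45037 simulated probe sets were shifted, and limma recovered 7 of 67 at a log2 shift of 0.5, 52 of 67 at 1 and 62 of 66 at 2, with 3 false calls. In the data 13228 probe sets changed, which makes the adjusted cut-off less strict than in the simulation. The recovered shares are therefore not the power of the fit to the data. Among simulated lists, camera called 3 of 3 that were shifted by 0.5 and 0 of 33 that were not, and with an estimated correlation it called 2 of the 3. The simulated noise was independent between probe sets, so this does not show how often camera calls lists of correlated genes wrongly. No column of per-sample values was left unused.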

Results

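T cells were purified by negative selection from individual spleens of male C57BL/6 mice aged 10 weeks, and their RNA was amplified and hybridized to Affymetrix 1-colour expression arrays. There were 3 arrays from mice lacking miR-142 (KO), a microRNA made across the blood lineages, and 3 from wild-type littermates (WT). The values were log2 probe-set intensities as deposited, with array medians from 5.70 to 5.77. The arrays were too few for more than coarse precision. Pearson correlations across probe sets, which are not independent replicates, were 0.994 to 0.996 between WT arrays, 0.986 to 0.995 between KO arrays and 0.940 to 0.965 between the genotypes. The hybridization controls, bacterial transcripts added at fixed amounts before hybridization, averaged 10.21 ± 0.10 (SD, n = 3) in WT and 9.85 ± 0.06 in KO. The 3' minus 5' difference of the Actb control probe sets, a sign of RNA integrity, was 0.20 ± 0.03 in WT and 0.36 ± 0.04 in KO. The 18S ribosomal controls averaged 9.55 ± 0.10 in WT and 8.73 ± 0.76 in KO, where KO replicate 1 stood apart at 7.86 against 9.15 and 9.19. Without it the 18S difference was -0.38 in place of -0.81. KO replicate 1 also had a Gapdh 3' minus 5' difference of 0.18 against -0.07 and -0.10 in KO replicates 2 and 3.

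The comparison of KO with WT asked which transcripts of splenic T cell preparations differ when miR-142 is absent, and E2f7 and E2f8 are the genes that the study is known to have followed up. The transcript listed as Mir142, which hosts the microRNA, fell 3.98-fold, from a log2 intensity of 7.91 ± 0.23 (SD, n = 3) in WT to 5.92 ± 0.05 in KO (limma adjusted p = 6.6e-05). E2f7, an atypical E2F factor that represses cell cycle genes, rose 9.86-fold, from 5.49 ± 0.44 to 8.79 ± 0.26 (limma adjusted p = 9.6e-05). Its close relative E2f8 rose 7.65-fold, from 8.09 ± 0.11 to 11.02 ± 0.22 (limma adjusted p = 2.1e-05). Every KO array lay above every WT array for both E2F genes and below every WT array for Mir142. In the same KO arrays, markers of neutrophils, mast cells, basophils and eosinophils averaged 10.43 ± 0.91 against 6.14 ± 0.29 in WT, and genes of the T cell receptor list averaged 9.75 ± 0.54 against 11.34 ± 0.03. A further probe set of E2f8 differed by 0.15 (limma adjusted p = 0.293). Whether the Mir142 probe set lies in the deleted part of the locus was not known here, so it checks the genotype labels only if it does, and the mature microRNA was not measured.

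**Figure D1:**
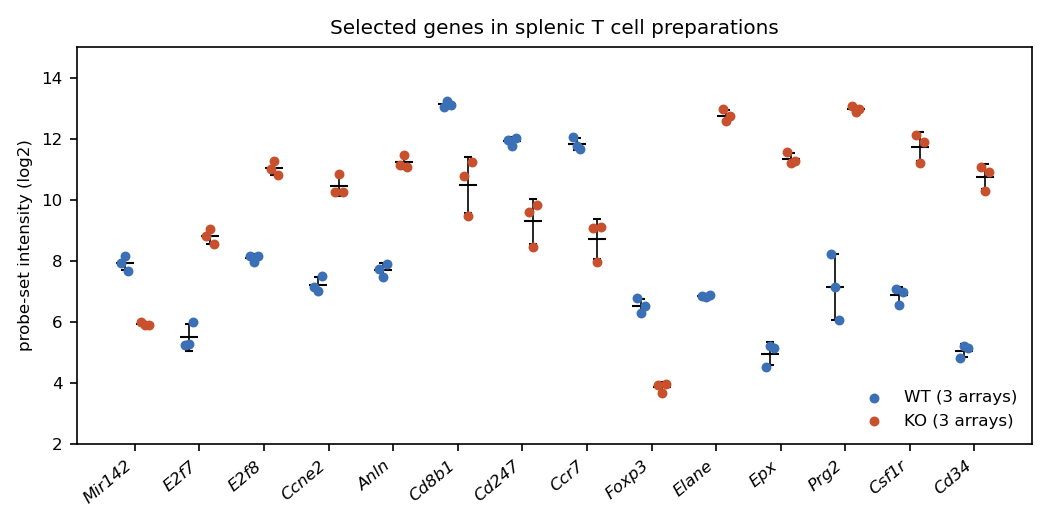
Probe-set intensity (log2, vertical axis) of 14 genes in 3 WT and 3 KO arrays, where each point is 1 array and bars give the mean ± SD. E2f7 and E2f8 averaged 8.79 and 11.02 in KO against 5.49 and 8.09 in WT, Cd8b1 and Ccr7 averaged 10.49 and 8.71 against 13.12 and 11.83, and Elane and Epx averaged 12.75 and 11.34 against 6.83 and 4.95.

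Of 45037 probe sets tested with limma, 6242 rose and 6986 fell in KO, and of 18194 genes, each taken at its brightest probe set, 3385 rose and 3379 fell. Chil3, a chitinase-like lectin of myeloid cells, rose 92.3-fold, from 4.42 ± 1.18 (SD, n = 3) to 10.95 ± 1.73 (limma adjusted p = 0.0016). Epx, the eosinophil peroxidase, rose 83.8-fold, from 4.95 ± 0.39 to 11.34 ± 0.19 (limma adjusted p = 9.5e-06). Elane, the neutrophil elastase, rose 60.4-fold, from 6.83 ± 0.02 to 12.75 ± 0.20 (limma adjusted p = 2.2e-06). S100a9 and S100a8, which form calprotectin, rose 74.1-fold and 69.0-fold, with WT values spread over 6.22 ± 2.23 and 6.82 ± 2.16. Mgst1, Ms4a3, Dmkn, Mcpt1, Prg2, Lyz2, Cd34, Anxa3, Lcn2 and Bex6 completed the 15 largest rises among the genes eligible for naming, which exclude predicted genes and receptor variable segments, from 80.7-fold for Mgst1 to 47.5-fold for Bex6. Some of these sizes rested on single arrays. Without KO replicate 1 the rises were 46.4-fold for Chil3, 39.1-fold for S100a9 and 17.8-fold for Lcn2, and without KO replicate 2 they were 139-fold, 119-fold and 97.4-fold. Without WT replicate 1 they were 147-fold for Chil3, 180-fold for S100a9 and 163-fold for S100a8, without WT replicate 2 40.6-fold for S100a8, and without WT replicate 3 45.5-fold for S100a9. The genes that fell most began with Ifit1bl1, a member of the interferon-induced Ifit family, which fell 16.7-fold from 11.46 ± 0.33 to 7.40 ± 0.56. Next came Dapl1, which is expressed in naive T cells and fell 13.9-fold from 11.75 ± 0.06 to 7.95 ± 0.78. Ctla4, an inhibitory receptor of T cells, fell 8.93-fold, and the chemokine receptors Cxcr5 and Ccr7, which guide lymphocytes within lymphoid organs, fell 8.72-fold and 8.70-fold. Tdrp, Lypd6b, Slc16a5, Klra7, Sema4f, Prg4, Sidt1, Vipr1, Gpr183 and Ntrk3 also stood among the 15 largest falls of eligible genes, from 13.6-fold for Tdrp to 7.29-fold for Ntrk3. At least 8-fold differences were seen for 180 genes that rose and 18 that fell. The median difference of all probe sets was -0.08 as deposited and 0.29 after each array was scaled to its hybridization controls. Under that scaling 17309 probe sets rose and 2337 fell, so that 88.1% of the changed probe sets were higher against 47.2% as deposited.

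Many markers of blood lineages other than T cells rose in KO. All 12 measured mast cell, basophil and eosinophil markers rose, both over all genes tested and adjusted over the list alone, with a median log2 difference of 4.21. In camera, mast cell, basophil and eosinophil markers had an adjusted p = 1.2e-11, and adjusted p = 0.454 with an estimated correlation. Among them Prg2, the eosinophil major basic protein, rose by 5.83 ± 0.47 (SE, n = 3 per group), Fcer1a, a chain of the high-affinity IgE receptor, by 4.94 ± 0.25, and the mast cell protease Mcpt4 by 4.89 ± 0.10. Of 14 neutrophil markers 11 rose, and 13 rose adjusted over the list alone, with a median of 4.88, which was 3.96 without KO replicate 1. The neutrophil markers had a camera adjusted p = 2.7e-07, and adjusted p = 0.461 with an estimated correlation. Of 22 monocyte and macrophage markers 10 rose (11 adjusted over the list alone, 18 under hybridization-control scaling), with a median of 1.22. That median ranged from 0.78 to 1.56 when each array was left out in turn. For monocyte and macrophage markers, the camera adjusted p was 1.1e-05, and adjusted p = 0.454 with an estimated correlation. Lyz1, a lysozyme, rose by 5.30 ± 0.44, Csf1r, the receptor of the macrophage growth factor, by 4.87 ± 0.25 and the Fc receptor Fcgr3 by 4.45 ± 0.24. The Lyz1 probe set can cross-hybridise with related genes. Of its 2 other probe sets 1 rose too and 1 differed by 0.38 (limma adjusted p = 0.138). Ctss, a lysosomal protease named after its values were seen, fell by 0.75, a call lost without WT replicate 1, 2 or 3 and under hybridization-control scaling. Of 15 dendritic cell markers 6 rose, also 6 adjusted over the list alone, among them Irf8 by 2.99 ± 0.18 and Tcf4 by 2.34 ± 0.18, transcription factors of dendritic cells. In camera, dendritic cell markers had an adjusted p = 0.015, and adjusted p = 0.461 with an estimated correlation. The markers of neutrophils and of mast cells, basophils and eosinophils averaged 6.47 in WT replicate 1 against 5.97 and 5.98 in WT replicates 2 and 3. Neutrophil markers averaged 12.32 in KO replicate 1 against 9.56 and 10.11 in KO replicates 2 and 3.

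Erythroid markers rose for 11 of 14 genes, also 11 adjusted over the list alone, with a median log2 difference of 2.11. The erythroid markers had a camera adjusted p = 1.4e-05, and adjusted p = 0.491 with an estimated correlation. The red cell membrane genes Slc4a1 and Epb42 rose by 4.81 ± 0.40 (SE, n = 3 per group) and 4.14 ± 0.46, and Rhag, of the Rh complex, by 3.60 ± 0.30. The alpha globin gene Hba-a2, named after its values were seen, was dim at 5.19 in WT and fell by 0.50, a call lost without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3 and under hybridization-control scaling. Of 11 megakaryocyte and platelet markers 7 rose, also 7 adjusted over the list alone, with a median of 1.38. For megakaryocyte and platelet markers, the camera adjusted p was 0.0028, and adjusted p = 0.454 with an estimated correlation. Among probe sets above the median level 4 rose and the call was lost (adjusted p = 0.073). The platelet chemokine Pf4 rose by 2.66 ± 0.16 and the integrin Itga2b by 2.08 ± 0.15, whereas Itgb3, an integrin chain named after its values were seen, fell by 0.94, a call lost without WT replicate 2 and under hybridization-control scaling. Among 19 progenitor and stromal markers, Cd34, Meis1, Kit, Gata2 and Vwf rose, the same number adjusted over the list alone, by 5.71 ± 0.21, 3.31 ± 0.13, 2.61 ± 0.12, 2.52 ± 0.16 and 1.76 ± 0.24. Kit and Gata2 also stand in the mast cell, basophil and eosinophil list, and Vwf in the megakaryocyte and platelet list. Their rises are counted there too and are not separate evidence of progenitors. Igfbp7, Pecam1 and Pdgfra, named after their values were seen, fell by 0.71, 0.59 and 0.45 (4 genes fell adjusted over the list alone, 1 without WT replicate 1 or 2, and 0 under hybridization-control scaling). This list was not called (camera adjusted p = 0.376, and adjusted p = 0.598 with an estimated correlation), and its median of -0.08, which turned to 0.01 without WT replicate 2 and to 0.28 under hybridization-control scaling, differed in sign from its mean of 0.70 and its test.

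Among markers of B cells, plasma cells, NK cells and immature thymocytes some rose and others fell. Of 20 B cell markers Blnk, Spib and H2-Ab1 rose by 2.34 ± 0.63 (SE, n = 3 per group), 2.15 ± 0.51 and 1.77 ± 0.41 and Cd72 fell by 1.10 ± 0.16, with Blnk at 1.56 without KO replicate 2. These counts stood at 3 and 1 adjusted over the list alone too. In camera, B cell markers had an adjusted p = 0.117, and adjusted p = 0.553 with an estimated correlation. The B cell list was called without WT replicate 1 (adjusted p = 0.034, 5 rose), KO replicate 2 (0.012, 7 rose) or KO replicate 3 (0.039), and also with the replicate number as a block (0.019, 6 rose) and without both WT replicate 1 and KO replicate 2 (0.00079, 10 rose). In contrast 0 rose without WT replicate 2 or 3, and 9 rose under hybridization-control scaling. Of 8 plasma cell markers Sdc1 and Xbp1 rose by 1.21 ± 0.28 and 0.64 ± 0.17 and Prdm1 fell by 1.19 ± 0.25, likewise adjusted over the list alone. The plasma cell markers had a camera adjusted p = 0.270, and adjusted p = 0.598 with an estimated correlation. The plasma cell list was called without WT replicate 1 (adjusted p = 0.016, 4 rose) and without both WT replicate 1 and KO replicate 2 (0.0070, 6 rose), while 0 rose without WT replicate 2 and 1 without WT replicate 3, KO replicate 1 or KO replicate 3, against 4 under hybridization-control scaling. WT replicate 1 had the highest B cell mean of the WT arrays, 7.55 against 7.07 and 6.95. It also had their highest plasma cell mean, 9.47 against 8.68 and 8.50. Leaving it out therefore enlarges both differences by construction. The calls of the B and plasma cell lists without it are thus no separate support for a rise. In the NK cell list of 15 genes, Tyrobp, Fcgr3 and Fcer1g, signalling adaptors and an Fc receptor that myeloid cells also express, rose by 4.81 ± 0.28, 4.45 ± 0.24 and 3.89 ± 0.28. From the same list 7 genes fell, among them the receptor Klra7 by 3.48 ± 0.31, with the same counts adjusted over the list alone. The NK list's median of -0.11, which turned to 0.26 under hybridization-control scaling with a call for lower genes (adjusted p = 0.016), differed in sign from its mean of 0.05. For NK cell markers, the camera adjusted p was 0.468, and adjusted p = 0.778 with an estimated correlation. Plac8, by 1.57 ± 0.10, was the gene that rose among 8 gamma delta and innate-like T cell markers, also adjusted over the list alone (2 rose with a repeated quantile normalization or with trend and robust fitting, 3 with median centring, array weights or the mean of probe sets, 3 without KO replicate 2 and 4 under hybridization-control scaling). Its list had a median of 0.06, which turned to -0.07 without KO replicate 1 and -0.03 without WT replicate 3, and a mean of the other sign, -0.03 (camera adjusted p = 0.376, and adjusted p = 0.646 with an estimated correlation). Of 12 immature thymocyte markers Cd24a, Hes1 and Sox4 rose by 2.55 ± 0.19, 1.41 ± 0.24 and 1.33 and Themis, Il2ra and Notch1 fell by 1.78 ± 0.29, 1.42 ± 0.20 and 1.41, Sox4 and Notch1 being named after their values were seen. Adjusted over the list alone 6 rose and 3 fell, and 7 rose without KO replicate 2, 6 without both WT replicate 1 and KO replicate 2, 5 with array weights and 6 under hybridization-control scaling. In camera, immature thymocyte markers had an adjusted p = 0.304, and adjusted p = 0.503 with an estimated correlation.

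**Figure D2:**
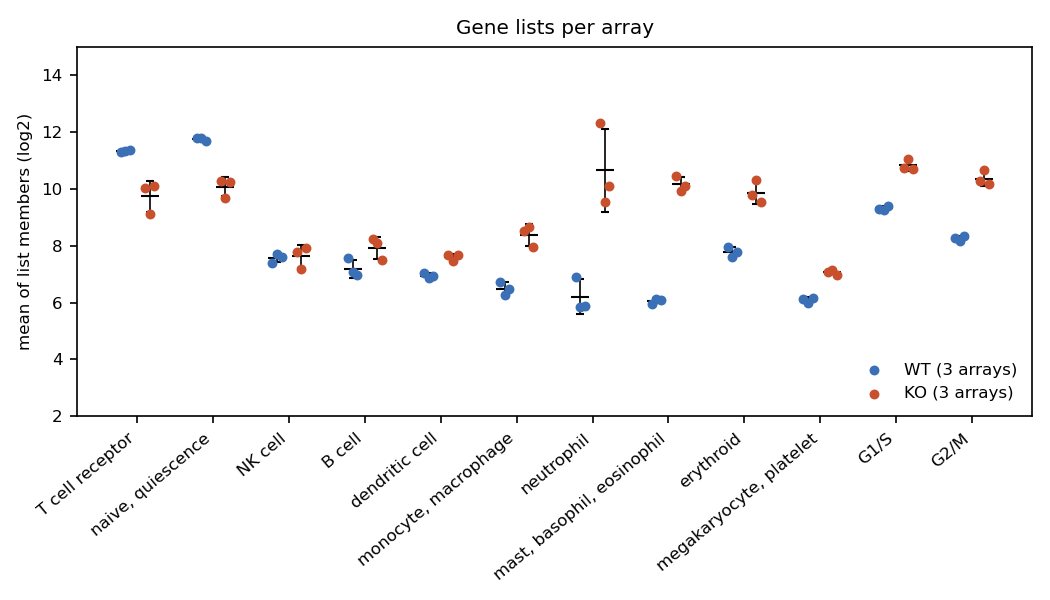
Mean log2 intensity of the members of 12 gene lists (vertical axis) in 3 WT and 3 KO arrays, where each point is 1 array and bars give the mean ± SD. The T cell receptor list averaged 11.34 in WT and 9.75 in KO, whereas NK cell markers averaged 7.57 and 7.62.

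Genes of T cells fell in KO. Of 32 genes of the T cell receptor complex and its proximal signalling 31 fell, also 31 adjusted over the list alone, with a median log2 difference of -1.65. The T cell receptor genes had a camera adjusted p = 4.9e-10, and adjusted p = 0.495 with an estimated correlation. Txk, a kinase of the receptor pathway, fell by 2.70 ± 0.33 (SE, n = 3 per group), and Cd247, the zeta chain of the receptor complex, fell by 2.63 ± 0.33. Of 10 CD8 lineage genes 7 fell and 8 adjusted over the list alone, led by the coreceptor chain Cd8b1, which fell by 2.63 ± 0.40 from 13.12 ± 0.09 (SD) to 10.49 ± 0.92 (camera adjusted p = 0.0029, and adjusted p = 0.503 with an estimated correlation). Without WT replicate 1 or 2, 4 CD8 lineage genes fell. Of 7 CD4 lineage genes Cd5, Izumo1r, Cd4, Gata3 and Tnfsf8, the last named after its values were seen, fell by 2.20 ± 0.36, 1.77 ± 0.20, 1.58 ± 0.23, 1.45 ± 0.23 and 1.37, also 5 adjusted over the list alone. For CD4 lineage genes, the camera adjusted p was 0.0035, and adjusted p = 0.503 with an estimated correlation. Cd5, the largest of these falls, also stands in the T cell receptor list and is not particular to the CD4 lineage. Izumo1r stands in the regulatory T cell list too, and Gata3 in the helper subset list. Naive and quiescence genes fell for 20 of 21 members, also 20 adjusted over the list alone, with a median of -1.80. In camera, naive and quiescence genes had an adjusted p = 1.1e-09, and adjusted p = 0.454 with an estimated correlation. Beside Dapl1 and Ccr7, the actin crosslinker Actn1 fell by 2.68 ± 0.30 and S1pr1, the receptor that lets T cells leave lymphoid organs, by 2.53 ± 0.26. KO replicate 2 had the lowest mean of the T cell receptor list, 9.12 against 10.02 and 10.11 in KO replicates 1 and 3. Markers of neutrophils, mast cells, basophils and eosinophils were higher by 4.29 in KO, and among KO arrays they were lowest in KO replicate 2 as well, 9.73 against 11.46 and 10.11.

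Many genes of T cell states fell too. Of 17 regulatory T cell genes 10 fell, also 10 adjusted over the list alone, with a median log2 difference of -1.31. The regulatory T cell genes had a camera adjusted p = 0.0016, and adjusted p = 0.503 with an estimated correlation. Foxp3, the master regulator of this lineage, fell by 2.66 ± 0.15 (SE, n = 3 per group) from 6.51 ± 0.24 (SD) to 3.85 ± 0.17, and Tnfrsf4, a costimulatory receptor, by 1.95 ± 0.20. The cytokine subunit Ebi3, named after its values were seen, rose by 1.04, a call lost without WT replicate 1, 2 or 3 or KO replicate 3, while 2 rose without KO replicate 2. Of 41 activation, effector and memory genes 22 fell and 6 rose, and 26 and 6 adjusted over the list alone, with a median of -0.91. Leaving out each array in turn, this median ranged from -1.02 to -0.55. For activation genes, the camera adjusted p was 0.0019, and adjusted p = 0.598 with an estimated correlation. The cytotoxic granule genes Gzmm and Prf1 fell by 2.62 ± 0.26 and 2.55 ± 0.21, whereas Anxa1 and the chemokine receptor Ccr2, which myeloid cells also express, rose by 3.82 ± 0.33 and 2.44 ± 0.27. Of 18 coinhibitory and exhaustion genes 10 fell, also 10 adjusted over the list alone, among them Egr3 by 1.98 ± 0.39 and Tox by 1.94 ± 0.26. Cd244a, named after its values were seen, rose by 0.67. In camera, coinhibitory genes had an adjusted p = 0.0044, and adjusted p = 0.503 with an estimated correlation. Helper subset regulators fell for 11 of 23 genes, and 14 adjusted over the list alone, among them Ifng by 1.86 ± 0.27 and Stat4 by 1.54 ± 0.21 (camera adjusted p = 0.0056, and adjusted p = 0.528 with an estimated correlation). In that list Ahr and Stat5a, named after their values were seen, rose by 1.08 and 0.37. The falls of helper genes numbered 7 without WT replicate 1 and 7 under hybridization-control scaling, and the rises numbered 1 without WT replicate 2, KO replicate 1 or KO replicate 3. Of 28 cytokine receptor and JAK-STAT genes 17 fell, and 18 adjusted over the list alone, led by the receptors Il7r by 2.29 ± 0.08 and Il18r1 by 2.26 ± 0.42. Ifngr2 and Ifnar2, named after their values were seen, rose by 0.88 and 0.74 (camera adjusted p = 0.0011, and adjusted p = 0.528 with an estimated correlation, with 11 falls and 4 rises under hybridization-control scaling). Of 29 adhesion and chemokine receptor genes 19 fell, and 20 adjusted over the list alone, with Gpr183 down by 3.01 ± 0.25 beside Cxcr5 and Ccr7. Ccr2, Cx3cr1 and Itgav, the last pair named after their values were seen, rose by 2.44 ± 0.27, 1.06 and 0.45. The adhesion genes had a camera adjusted p = 0.00039, and adjusted p = 0.503 with an estimated correlation. The falls of that list numbered 12 without WT replicate 2 and 12 under hybridization-control scaling. Beside these lists, Cd3d, Cd3e and Cd3g averaged 12.72 ± 0.03 in WT and 11.08 ± 0.76 in KO.

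Cell cycle genes rose in KO. Of 37 G1/S and DNA replication genes 35 rose, also 35 adjusted over the list alone, with a median log2 difference of 1.37. For G1/S genes, the camera adjusted p was 7.9e-19, and adjusted p = 0.454 with an estimated correlation. Ccne2, the cyclin that starts replication with Cdk2, rose by 3.24 ± 0.20 (SE, n = 3 per group), the licensing factor Cdc6 by 2.67 ± 0.18 and the thymidine kinase Tk1 by 2.62 ± 0.16. Of 35 G2/M and mitosis genes 33 rose, also 33 adjusted over the list alone, with a median of 2.29. In camera, G2/M genes had an adjusted p = 2.9e-20, and adjusted p = 0.454 with an estimated correlation. Anln, needed for cytokinesis, rose by 3.54 ± 0.15, and the mitotic kinase Aurkb by 2.88 ± 0.17, while Pttg1, the securin, named after its values were seen, fell by 0.99. Of 18 E2F, pocket protein and DREAM genes 12 rose and 13 adjusted over the list alone, with Mybl2 and E2f1 up by 2.58 ± 0.19 and 1.90 ± 0.17 beside E2f7 and E2f8. The E2F and DREAM genes had a camera adjusted p = 0.00083, and adjusted p = 0.491 with an estimated correlation. E2f5, Rbl2, Lin52 and Lin37, named after their values were seen, fell by 0.83, 0.71, 0.44 and 0.31, also 4 adjusted over the list alone (2 without WT replicate 2, 2 with the replicate number as a block and 0 under hybridization-control scaling). Among 12 CDK inhibitors and D cyclins, Ccnd1 rose by 2.76 ± 0.22, Cdk6 by 2.00 ± 0.11 and the inhibitor Cdkn1a by 1.58 ± 0.13. Of that list 6 genes rose in all, also 6 adjusted over the list alone, and Ccnd2 and Cdkn2d, named after their values were seen, fell by 1.14 and 0.85, where 5 fell with the mean of each gene's probe sets. For CDK inhibitors and D cyclins, the camera adjusted p was 0.106, and adjusted p = 0.461 with an estimated correlation. Both cell cycle lists together averaged 8.81 ± 0.08 (SD) in WT and 10.61 ± 0.23 in KO, in the same arrays in which neutrophil, mast cell and erythroid markers rose and T cell receptor genes fell. KO replicate 2 had the highest mean of the cell cycle lists, 10.87, and of erythroid markers, 10.31.

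Of 25 genes reported elsewhere as miR-142 targets, 11 rose and 8 fell in KO, and 11 and 10 adjusted over the list alone. E2f7 and E2f8 head this list and were followed up by the study, so they are not independent evidence of its direction. The actin-severing protein Cfl2 rose by 2.81 ± 0.11 (SE, n = 3 per group) and the adaptor Gab1 by 2.75 ± 0.32, whereas Tgfbr2, the type II receptor of TGF-beta, fell by 1.91 ± 0.22. The list was not called (camera adjusted p = 0.290, and adjusted p = 0.503 with an estimated correlation), and 16 of its members stand in other lists too. Its median of 0.09 was -0.01 among genes above the median level, -0.02 with the mean of each gene's probe sets, and 0.46 under hybridization-control scaling, where 13 members rose and 3 fell. The fry test called it higher (adjusted p = 0.00090). Seed matches were not searched.

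Some genes of the energy metabolism and MYC lists rose and a few fell. Of 28 glycolysis and MYC genes 12 rose, and 14 adjusted over the list alone, among them Hk2, the hexokinase of proliferating cells, by 2.49 ± 0.22 (SE, n = 3 per group) and the transferrin receptor Tfrc by 1.80 ± 0.20. Tfrc is not an enzyme of energy metabolism and also stands in the erythroid list. The glucose transporter Slc2a1 fell by 1.35 ± 0.20 and Pfkp and Hif1a, named after their values were seen, fell by 1.02 and 0.42. In camera, glycolysis and MYC genes had an adjusted p = 0.0027, and adjusted p = 0.454 with an estimated correlation. Under hybridization-control scaling 21 rose and 1 fell. Of 31 oxidative phosphorylation genes 18 rose, also 18 adjusted over the list alone, with a median of 0.33, among them Sdhc by 0.77 ± 0.14 and Sdhd by 0.63 ± 0.10 (camera adjusted p = 3.1e-05, and adjusted p = 0.503 with an estimated correlation), and Cox7c fell by 0.86 ± 0.23. The rises numbered 9 without WT replicate 1, 8 without WT replicate 2, 11 without KO replicate 2 or 3, 5 without both WT replicate 1 and KO replicate 2, 9 with the replicate number as a block, and 29 under hybridization-control scaling. The Cox7c call was lost without WT replicate 1, WT replicate 2 or both WT replicate 1 and KO replicate 2, with the block (adjusted p = 0.073) and under hybridization-control scaling. These lists moved in the arrays in which erythroid markers rose by a median of 2.11.

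Interferon-stimulated, actin and TGF-beta genes were lower or mixed. Of 39 interferon-stimulated genes 25 fell, and 26 adjusted over the list alone, with a median log2 difference of -0.67. The interferon-stimulated genes had a camera adjusted p = 0.00072, and adjusted p = 0.461 with an estimated correlation. Slfn1, tied to T cell quiescence, fell by 2.49 ± 0.32 (SE, n = 3 per group), Ifit3 by 1.83 ± 0.27, and Ifi27l2a fell by 1.79 ± 0.11. The interferon genes Isg20, Rsad2, Ifi204 and Gbp3, named after their values were seen, rose by 1.44, 1.26, 1.26 and 0.66 (9 genes rose under hybridization-control scaling). Of 37 actin cytoskeleton and migration genes 19 fell and 22 adjusted over the list alone, with the GTPase Rhoh down by 1.80 ± 0.10 and a median of -0.37, which was -0.00 under hybridization-control scaling. Vcl, which links actin to adhesions, rose by 2.74 ± 0.14 beside Cfl2, Wasl and Coro2a, the last pair named after their values were seen, by 2.81 ± 0.11, 1.11 and 0.87. For actin genes, the camera adjusted p was 0.0087, and adjusted p = 0.528 with an estimated correlation. With that scaling 9 actin genes rose and 7 fell. Of 19 TGF-beta signalling genes 6 rose and 10 fell, and 6 and 11 adjusted over the list alone, among them the receptors Acvr1 up by 2.16 ± 0.12 and Tgfbr2 down by 1.91 ± 0.22. In camera, TGF-beta genes had an adjusted p = 0.248, and adjusted p = 0.528 with an estimated correlation. Scaling to the hybridization controls left 6 TGF-beta falls and a call for lower genes (camera adjusted p = 0.0077). The T cell receptor list fell in the same arrays by a median of 1.65.

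**Figure D3:**
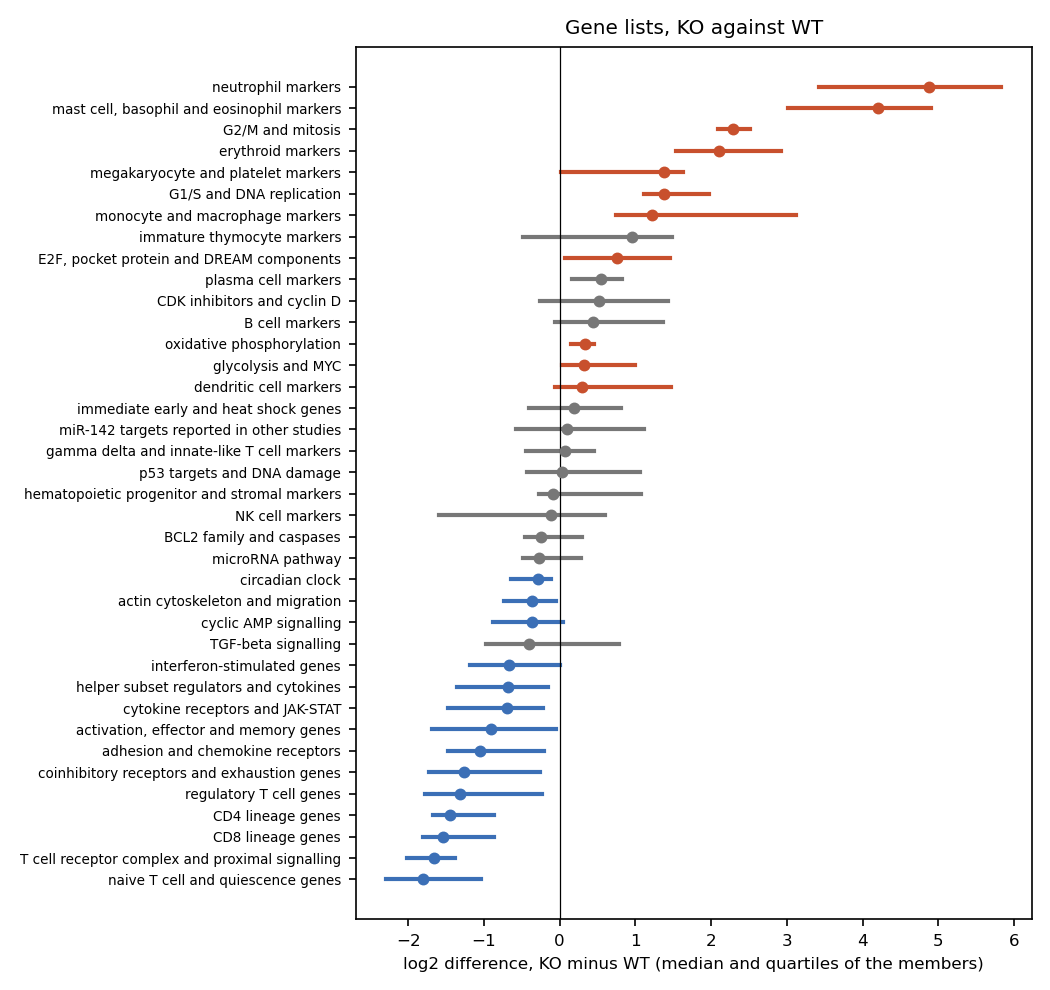
Median log2 difference, KO minus WT (horizontal axis, with quartiles of the members as lines), of 38 gene lists, from 3 arrays per group. Red marks lists that camera called higher with its preset correlation, such as neutrophil markers at 4.88, blue those called lower, such as naive and quiescence genes at -1.80, and grey those not called, and under hybridization-control scaling the medians of the BCL2 family, microRNA pathway, clock, NK cell and progenitor lists turned to 0.12, 0.10, 0.08, 0.26 and 0.28.

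Of the 38 lists, camera called 11 higher and 14 lower with its preset correlation, and none of these calls held with a correlation estimated from the data, where the smallest adjusted p was 0.454. The fry test, which asks whether the genes of a list move on balance one way and compares them with no other genes, called 16 higher and 14 lower. It did not call the activation list (adjusted p = 0.055), and it called the lists of CDK inhibitors, p53 targets, miR-142 targets, TGF-beta signalling, progenitors and immature thymocytes, which camera did not. Other probe sets of the named genes kept direction and call in 109 cases, kept the direction without a call in 45, among them those of Vcl, Prf1, Slfn1, Cd247 and Lyz1, and went the other way without a call in 15. Camera with the preset correlation also called 8 to 24 lists when the 6 arrays were divided otherwise than by genotype. Each such split mixes the genotypes unevenly and keeps part of their difference, so these counts do not show what camera calls without one. Groups did not overlap for 20681 probe sets (45.9%), where chance alone gives 10%.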

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

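The tests of explanations in this part were chosen after the results they address had been seen, and the counts over splits of the arrays were planned. With 6 arrays there are 10 splits into 3 and 3, which cannot give a share under 0.05, and in each case below 1 split, the real one, gave as many. The real split gave 13228 changed probe sets and the highest other split 2, the real split gave 6764 changed genes and the highest other 0, and the real split gave 25 called lists and the highest other 24, with WT replicate 1 grouped with KO replicates 1 and 2. Each other split mixes the genotypes unevenly, so it keeps part of their difference and adds the rest to the spread within groups. Its counts therefore do not show what chance alone gives.

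Some array control probe sets, which the comparison of genotypes left out, differed between KO and WT. Those below detect transcripts of mouse genes, unlike the hybridization controls, so a change in expression or cell composition can move them. For each of those below, every KO array lay above every WT array, and differences are between group means on the log2 scale. The Gapdh 3' control differed by 0.625. The middle Gapdh control differed by 0.605. The 3' control of pyruvate carboxylase differed by 0.687, with 7.51, 7.69 and 7.13 in the KO arrays against a WT mean of 6.76. The 3' control of the transferrin receptor differed by 1.02, with 6.49, 7.56 and 6.65 in KO against 5.89. Its 5' control differed by 0.833, and by 0.357 without KO replicate 2. Its middle control differed by 0.666, and by 0.279 without KO replicate 2. The tested probe set of Tfrc, the gene of this receptor and a member of the erythroid list, rose by 1.80. It too was highest in KO replicate 2, with 12.29, 12.97 and 12.19 in the KO arrays. These control differences are therefore not by themselves a sign of an array fault.

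Genes of neutrophils, mast cells, basophils and eosinophils were higher in KO, with 23 of 26 markers past the threshold; of the 26, 2 stand in other lists, while 10 of 14 neutrophil and 6 of 12 mast cell, basophil and eosinophil markers lay above the median of all probe sets in WT. A lower share of T cells alone would raise markers of every other cell type alike, but these markers rose by 3.89 ± 0.43 (log2, SE of the difference between group means, as for each ± in this part) more than those of B and NK cells. This argues against it as far as those lists serve as references. The NK list is a weak reference, since 6 of its 15 genes also stand in lists of T cell or monocyte genes. Among them Klrd1, also a CD8 lineage gene, fell by 1.64. In the B cell list Cd72 stood at 10.26 in WT and fell by 1.10, and the count of rises changed with the arrays kept. Genes that fall with T cells lower such a reference, so the size of the gap is uncertain. B cell markers alone were higher in KO by 0.74, against 4.29 for granulocyte and mast markers. Array scaling is argued against too, since the hybridization controls were lower in KO by 0.37 (-0.37 ± 0.07), so that correcting for them would enlarge the rise. The 23 markers, with Prg2, S100a8 and Elane at 12.97, 12.93 and 12.75 in KO, are consistent with granulocyte and mast lineage cells, mature or immature, in the KO preparations, although negative selection is meant to remove such cells, and within KO their level did not follow the loss of T cell genes, since KO replicate 2 was lowest in both, at 9.73 and 9.12. More of these cells in KO spleens, a purification that left more of them, and expression of their genes in T cells stay open as hypotheses, and an effect of the genotype was not separated from these.

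Cell cycle genes, E2f7 and E2f8 were higher in KO, the cell cycle lists by 1.80 ± 0.14. Array scaling is argued against, since the hybridization controls shifted the other way, by -0.37. Dividing cells of other lineages in the KO preparations could contribute. The KO array with the lowest T cell receptor list, KO replicate 2, lay 0.40 above the other KO arrays in cell cycle genes. The SD of these genes was 0.08 among WT arrays and 0.23 among KO arrays, the latter including KO replicate 2. Among KO arrays it was highest in erythroid (10.31), monocyte and macrophage (8.65), megakaryocyte and platelet (7.16) and immature thymocyte markers (9.03). It was lowest in granulocyte and mast markers and in NK cell (7.17) and dendritic cell markers (7.48). With 3 KO arrays and no sorted fractions, such cells and division of the T cells themselves cannot be told apart. Loss of repression of E2f7 and E2f8 by miR-142 in T cells stays open as a hypothesis that these arrays did not test apart from cell composition.

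T cell genes were lower in KO. As whole lists, naive and quiescence genes differed from T cell receptor genes by -0.10 ± 0.14, less than its SE, which is consistent with a common dilution of T cells. Gene by gene there were differences: relative to the mean of Cd3d, Cd3e and Cd3g, 13 of 65 T cell genes were lower and 12 higher in KO (limma, adjusted over these genes), and 40 did not pass. The 13 lower genes included Dapl1 at -2.16 and Cd8b1 at -0.99, whereas Cd8a at -0.21 and Cd4 at 0.06 did not pass. The 12 higher ones ran from Ubash3a at 0.86 to Dok1 at 1.86. Which of them other blood cells in the KO preparations express was not tested. These differences argue against dilution as the whole cause only if all probe sets respond alike to it, which was not tested. For the 12 higher genes this also requires that the other cells present do not express them. A changed make-up of the T cells and a change within them stay open and were not tested.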

How the results depend on the processing

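Scaling to the hybridization controls and leaving out WT replicate 1 with KO replicate 2, here called the 2 doubted arrays, were chosen after the results were seen. The other alternatives were planned. Array weights were 1.25 for WT replicate 1, 0.73 for WT replicate 3 and 0.44 for KO replicate 2. By this measure there was no ground to doubt WT replicate 1. Counts of changed probe sets and genes stayed within 1.5 times their values under all alternatives but hybridization-control scaling and the 1.5-fold minimum. Scaling to the hybridization controls gave 17309 rises and 2337 falls of probe sets and 7793 and 1314 of genes, with 88.1% of changed probe sets higher, because it adds one shift per array. A minimum of 1.5-fold left 3856 probe sets and 1958 genes lower, by its construction. With an estimated correlation 0 lists were called higher and 0 lower, and the cause was not tested. The replicate number as a block gave 5296 rises and 5117 falls, although the labels pair no samples. After each probe set's group mean was subtracted, same-numbered WT and KO arrays correlated at 0.10, -0.24 and -0.20. Leaving out each array in turn gave 4725 to 5963 rises and 4685 to 6387 falls. Without the 2 doubted arrays 5019 probe sets rose and 5244 fell, and 13 lists were called each way. An adjusted p below 0.10 gave 7326 and 9318. Of the named genes 151 of 156 kept direction and call under hybridization-control scaling (Ptger2, Cox7c, Zc3h12a, Ago3 and Rora lost the call). The mean of a gene's probe sets ended the calls of Bcl2, Ndufb8, Ago3 and Per3, the block those of Ptger2, Cox7c and Rora, the trend with robust fitting those of Hspa1b and Blnk, and leaving out the 2 doubted arrays that of Cox7c. Leaving out 1 array kept 910 results of named genes and ended 26, those of Bcl2, Klrd1, Cox7c, Hspa1b, Rora, Ptger2, Blnk, Spib, H2-Ab1, Sdc1 and Xbp1. The call of the megakaryocyte list was lost among genes above the median level (adjusted p = 0.073). Signal near background, where RMA compresses differences, limits what dim probe sets show.

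Values that reversed were the following, and the cause was not tested except under hybridization-control scaling, which by construction moves every median up by 0.37. Among genes above the median level the median of reported miR-142 targets was -0.0087 and that of gamma delta markers -0.063. With a repeated quantile normalization that of p53 targets was -0.012. With the mean of each gene's probe sets that of miR-142 targets was -0.019. Leaving out 1 array at a time, progenitor and stromal markers ranged from -0.087 to 0.0092 and gamma delta markers from -0.066 to 0.21. Scaled to the hybridization controls, medians were 0.12 for the BCL2 family, 0.10 for the microRNA pathway, 0.081 for the clock, 0.26 for NK cells and 0.28 for progenitors, while immediate early genes at 0.56, gamma delta markers at 0.43 and immature thymocyte markers at 1.32 turned in the direction of the camera test. The fry direction was up for the BCL2 family, whose median was -0.25. Other probe sets went the other way, none past the threshold, by -0.090 for Mgst1, -0.061 for E2f1, -0.19 for Brca1, -0.13 for Chek1, -0.16 for Acvr1, -0.017 for Bmpr2, 0.045 for Ago3, 0.10 for Rora, -0.19, -0.012 and -0.044 for Per3, -0.11 for Sdc1, -0.068 for Xbp1, -0.24 for Slc4a1 and -0.21 for Meis1. Of the other probe sets of named genes 109 kept direction and call, and 45 kept the direction without a call, among them those of E2f8 (0.15), Vcl (0.23), Prf1 (-0.32), Slfn1 (-0.14), Cd247 (-0.22) and Lyz1 (0.38).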

Other observations

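The lists of this part were fixed in advance, and the scaling to hybridization controls and the leaving out of WT replicate 1 with KO replicate 2 were chosen after the results were seen. Genes of cell death and DNA damage were mixed. Of 24 p53 target and DNA damage genes 8 rose and 7 fell, the same adjusted over the list alone, with the repair gene Brca1 and the checkpoint kinases Chek2 and Chek1 up by 2.51 ± 0.14 (SE, n = 3 per group), 2.41 ± 0.25 and 2.10 ± 0.15. The p53 target Cdkn1a, also in the list of CDK inhibitors, rose by 1.58 ± 0.13. In the same arrays 35 of 37 G1/S and DNA replication genes rose, and a DNA damage response was not tested apart from cell division. The list of p53 target and DNA damage genes had a camera adjusted p = 0.376, and adjusted p = 0.598 with an estimated correlation. Scaling to the hybridization controls left 4 falls. In the BCL2 family and caspases 9 of 21 genes fell, and 10 adjusted over the list alone, with the survival gene Bcl2 down by 1.25 ± 0.30 and the inhibitors Birc3 and Cflar by 1.21 ± 0.24 and 1.21 ± 0.23. The proapoptotic genes Bid, Bak1 and Apaf1 rose by 1.17 ± 0.08, 1.06 and 0.62, and Bcl2l2, a survival gene, by 1.14, where Bak1, Apaf1 and Bcl2l2 were named after their values were seen. Of this family 4 fell without WT replicate 1 or 2, with the Bcl2 call lost in each (adjusted p = 0.058 and 0.068), 5 fell without both WT replicate 1 and KO replicate 2, and 8 rose and 3 fell under hybridization-control scaling. The mean of its probe sets gave no call for Bcl2 (adjusted p = 0.074). The median of the family, -0.25, differed in sign from the fry direction, and was 0.12 under hybridization-control scaling. For the BCL2 family, the camera adjusted p was 0.544, and adjusted p = 0.606 with an estimated correlation. These lists moved in arrays in which the T cell receptor list fell by a median of 1.65.

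Stress, clock, cyclic AMP and microRNA pathway genes moved in both directions. Of 26 immediate early and heat shock genes 8 rose and 7 fell, and 11 and 8 adjusted over the list alone, with the AP-1 gene Fosb up by 2.92 ± 0.55 and Klf4 by 2.76 ± 0.31. In camera, immediate early genes had an adjusted p = 0.376, and adjusted p = 0.745 with an estimated correlation. Without WT replicate 1 there were 4 falls, and 13 rose under hybridization-control scaling. Of 17 clock genes 8 fell, and 10 adjusted over the list alone, with Dbp, a clock output gene, down by 1.39 ± 0.15. Per3 and Hlf, the latter named after its values were seen, rose by 0.89 ± 0.14 and 0.61. For Per3 the mean of its probe sets gave 0.14 without a call (adjusted p = 0.227), and 0 of its 5 other probe sets passed. The clock list's median was -0.29, and 0.08 under hybridization-control scaling, where 3 rose and 2 fell and the list was still called lower (adjusted p = 0.013). The clock genes had a camera adjusted p = 0.045, and adjusted p = 0.503 with an estimated correlation. The call of the clock list was lost without WT replicate 2, WT replicate 3 or KO replicate 2 (adjusted p = 0.056, 0.063 and 0.103), without both WT replicate 1 and KO replicate 2 (0.104) and among genes above the median level (0.064), and 5 of its genes fell without WT replicate 1, 2 or 3. Of 21 cyclic AMP genes 11 fell, and 12 adjusted over the list alone, with the adenylyl cyclase Adcy3 and the phosphodiesterase Pde7a down by 1.54 ± 0.11 and 1.38 ± 0.16. The cyclases Adcy6 and Adcy9, the latter named after its values were seen, rose by 1.07 ± 0.12 and 1.01. For cyclic AMP genes, the camera adjusted p was 0.030, and adjusted p = 0.454 with an estimated correlation. Under hybridization-control scaling 5 cyclic AMP genes rose and 5 fell, around a median of -0.00. Of 16 microRNA pathway genes 7 fell, and 8 adjusted over the list alone, among them the RNase Zc3h12a by 0.74 ± 0.13. Ago4, an Argonaute, rose by 1.77 ± 0.25, Prkra, a Dicer partner, by 1.57 ± 0.13, and Xpo5, named after its values were seen, by 0.60. In camera, microRNA pathway genes had an adjusted p = 0.451, and adjusted p = 0.637 with an estimated correlation. The median of the microRNA pathway list was -0.27, and 0.10 under hybridization-control scaling, with 6 rises and 0 falls. Markers of neutrophils, mast cells, basophils and eosinophils were higher by 4.29 in the same arrays.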
